A study of Rattus norvegicus with 12 samples.

How the data were processed

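Total RNA was extracted with Trizol from frozen prefrontal cortex, and libraries were made with an Illumina NEBNext kit, per the labels' protocols. The kit's strand setting and the sequencing run are not given in the sources used here. The submitters' processing notes list HTSeq 0.6.0 and the rat build Rnor_6.0, with no role for either. The aligner and the assembler are not given in the sources used here.

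The deposited table of the whole series held estimated counts in 78025 transcript rows for 12 libraries. The authors call these values read counts, but the values themselves behaved as estimated counts. Each was the FPKM value of the deposited per-sample file multiplied by a factor of the row and a factor of the library, rounded up to a whole number. Over the 12003 rows above 2000 in every library, the deviation from that product had a median of 0.0011% and a 99th percentile of 0.019%, against a median of 16.5% with the rows of the FPKM files shuffled. The per-sample files held FPKM values that the authors deposited per transcript row and labelled by gene identifier. Their unit was read from the values, because neither the files nor the labels name it. The rows of both kinds of file stood in the same order, and the product above was the check that transcript and gene identifiers could be paired by row. Of the rows, 41078 had an Ensembl transcript identifier and 36947 an identifier given by an assembler, of which 21164 lay in genes with an Ensembl identifier. Among genes with a mean estimated count of 300 to 3000, the variance between replicates was 69.4, 117 and 70.9 times the mean in the normal, HIBD model and acupuncture groups (medians). These ratios hold the biological spread between libraries as well as the noise of counting. What a value of 1 is worth in reads, and the depth in reads, are therefore unknown, and a 0 is given only as listed at 0. The table names no reads outside genes.

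Transcript values were summed per gene, giving 43206 genes, of which 35754 were above 0 in any library. Single transcripts were less stable than genes. Of transcripts with at least 10 CPM in a library, 7.5%, 7.6% and 7.3% were at 0 in another library of the same group (normal, HIBD model, acupuncture), against 0.38%, 0.41% and 0.3% of genes. No pair of libraries was a duplicate: Pearson's r across genes lay between 0.913 and 0.982. All per-sample value columns were used.

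The design was fixed before the data were examined. The summed estimated counts, whole numbers as deposited, were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM normalization, filterByExpr by group) in R 4.3.3, with all 12 libraries in 1 fit and no covariate. P-values were adjusted by the Benjamini-Hochberg method over 27885 genes, with a threshold of 0.05. The design had assumed counts of reads, and the same test was kept for the estimated counts. CPM values are estimated counts relative to the TMM-scaled library total, given as mean ± SD. Standard errors of log2 fold changes were derived from the F statistic. Comparisons of 1 value per library used two-sided exact permutation tests over the 70 assignments of 8 libraries, adjusted over 3 comparisons per measure. Alternatives fixed in advance were RLE normalization, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of at least 1 CPM in 4 libraries, fits of 2 groups only, transcript rows, 1 surrogate variable (sva 3.50.0), limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the 10 most abundant genes left out, an absolute log2 fold change of at least 1, and each replicate left out in turn. The removal of a length trend, an on/off class of libraries as covariate, division of the values by 70, Ensembl genes only, limma-voom with quality weights per library, and the settings for the assembled loci and the replicate spread were added after seeing the data.

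The rule for named genes fixed in advance needed gene symbols, as did 50 gene lists with 788 symbols, including markers of cell types. None of the 32883 Ensembl gene identifiers matched the reference table (assembly GRCr8), which held 762 of those symbols and no Ensembl identifiers. Gene lists, cell type markers, sex-linked genes and fixed marker genes were therefore not analysed here. For the comparisons of HIBD model with normal and of acupuncture with HIBD model, the 2 higher and 2 lower identifiers of lowest p with a mean log2 CPM of at least 0 are named instead. Some of them are also given for acupuncture against normal, beside the identifiers that the same rule picks there. All of these were chosen after their values were seen. Circular RNA was not analysed here.

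The test was run on simulated data for the comparison of HIBD model with normal. Values were drawn from the means and library totals of the real libraries at an assumed 70 units per read. Each group had 1 replicate spread for all genes. It was the median SD as a share of the mean, over genes with a mean estimated count of at least 30000. These spreads were 8.5%, 14.57% and 9.03% in the normal, HIBD model and acupuncture groups. Genes with lower values can vary more, so the shares recovered may be too high for them. In 1 set, 200 genes with a mean log2 CPM of at least 0 were changed, 50 at each fold, and 25623 genes were tested. Changes of 1.5-fold, 2-fold, 3-fold and 4-fold were recovered in 52%, 94%, 100% and 100% of genes, with 6 unchanged genes called. With the leading variation between libraries of the same group added, 25711 genes were tested and the shares were 16%, 66%, 88% and 100%. There 0 unchanged genes were called, but this could not show false calls from a gradient that differs between groups. The added variation was taken around the group means. Sets with no changed gene gave 0 calls, with the same limit where that variation was added. Shares of signs to set beside the real ones were taken from 100 simulated sets of 3 unchanged groups. They cover the same number of genes with the strongest difference between the simulated HIBD model and normal groups.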

Results

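RNA from the prefrontal cortex of SD rats at postnatal day 28 was sequenced in 12 libraries. The labels place 4 libraries in a normal group, 4 in a group with hypoxic-ischemic brain damage (HIBD), called the HIBD model group, and 4 in an acupuncture group. The labels of the acupuncture group name only the treatment, and the title of the series places acupuncture in rats with such damage. Each library carries its own number in the labels, which is used here as its replicate number. The labels do not say in words that each number is 1 animal, so the p-values measure the spread between these libraries. The deposited table of estimated counts held 43206 genes once its transcripts were summed, of which 32883 had an Ensembl identifier and 10323 were loci named by a transcript assembler, called assembled loci here. The total estimated count was 1012315386 ± 60877526 (SD, n = 4) in the normal group, 944505656 ± 97283929 in the HIBD model group and 899446399 ± 138254815 in the acupuncture group, and single libraries ranged from 714904584 to 1090316733. What 1 unit of these values is worth in reads is not known, so the totals are not given as numbers of reads and no counting interval is given. The files do not pair gene identifiers with gene names, so single genes are given by identifier, without a function.

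The comparison of the HIBD model with normal libraries asks what the injury model changed in this tissue. Gene ENSRNOG00000005927 rose from 16.1 ± 1.67 CPM (estimated counts relative to the TMM-scaled library total) in normal to 26.6 ± 0.861 CPM in HIBD model libraries (SD, n = 4 each), a log2 fold change of 0.72 (SE 0.08, edgeR quasi-likelihood test, adjusted p = 0.0199). Gene ENSRNOG00000004926 rose from 6.64 ± 0.482 to 10.2 ± 0.827 CPM, a log2 fold change of 0.62 (SE 0.08, edgeR adjusted p = 0.0398). Gene ENSRNOG00000000989 fell from 11.9 ± 1.42 to 6.21 ± 0.145 CPM, a log2 fold change of -0.93 (SE 0.12, edgeR adjusted p = 0.0372). Gene ENSRNOG00000054291 fell from 27.1 ± 1.78 to 17.5 ± 1.01 CPM, a log2 fold change of -0.63 (SE 0.08, edgeR adjusted p = 0.0372). In each of these 4 genes, the levels of the 4 HIBD model libraries lay outside the range of the 4 normal libraries. The genes were chosen by lowest p, so such separation adds no support. Each call was lost when certain single libraries were left out, with the direction kept. The call of ENSRNOG00000005927 was lost without normal replicate 8 or 11 or HIBD model replicate 8, 16 or 18 (edgeR adjusted p from 0.0509 to 0.0584). That of ENSRNOG00000004926 was lost without normal replicate 8, 11 or 13 or HIBD model replicate 8 or 16 (edgeR adjusted p from 0.0597 to 0.104). That of ENSRNOG00000000989 was lost without normal replicate 8 or 11 or HIBD model replicate 8, 16 or 18 (edgeR adjusted p from 0.0767 to 0.104). That of ENSRNOG00000054291 was lost without normal replicate 8, 11 or 13 or HIBD model replicate 8, 16 or 18 (edgeR adjusted p from 0.0733 to 0.102).

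**Figure D1:**
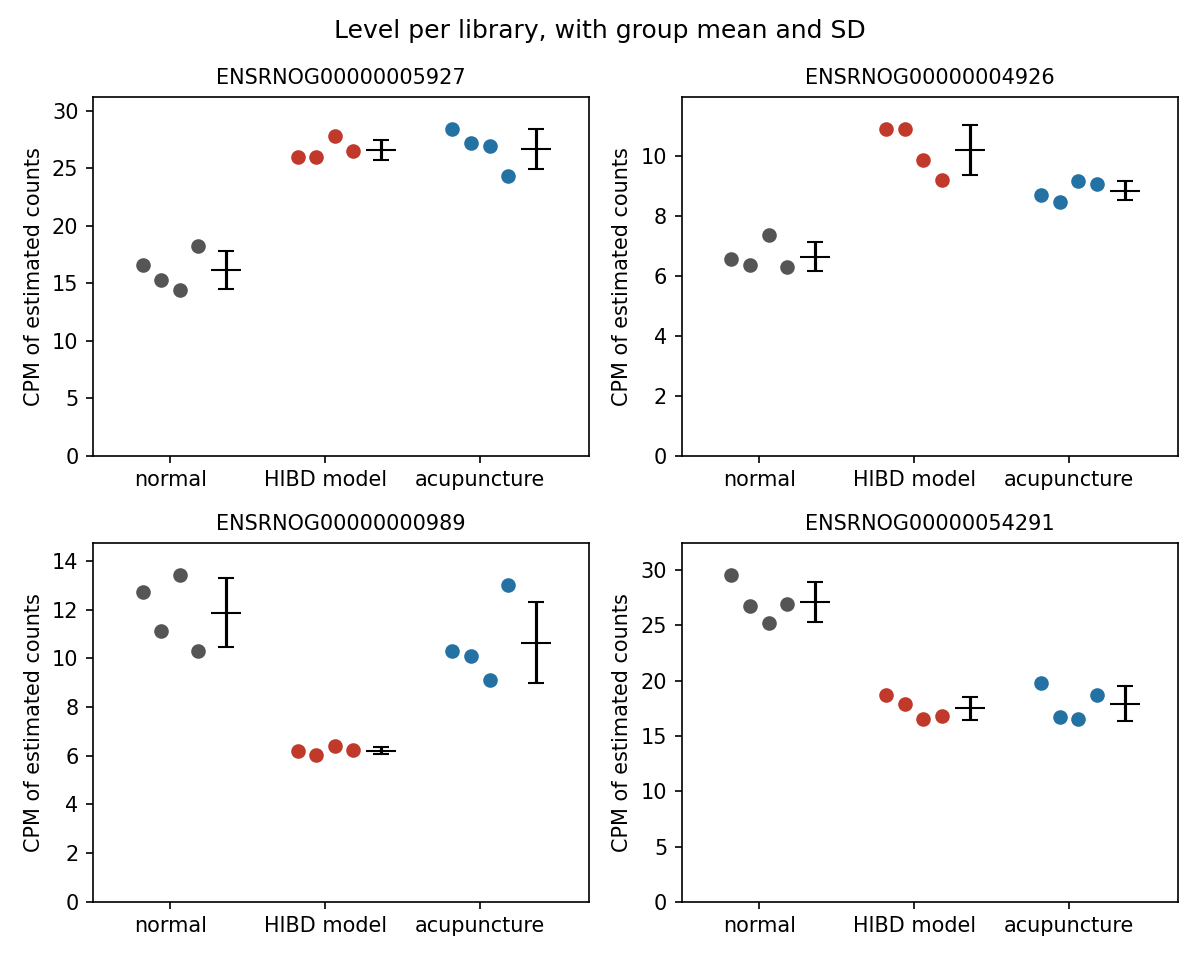
Level of 4 genes in each library, in CPM of the estimated counts (vertical axis, from 0), by group (horizontal axis). Points are libraries in the order of their replicate numbers, and bars give the group mean and SD (n = 4). ENSRNOG00000000989 averaged 6.21 CPM in the HIBD model group and 10.6 CPM in the acupuncture group, and ENSRNOG00000005927 averaged 26.6 and 26.7 CPM.

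Of 27885 genes tested, 27 passed an adjusted p of 0.05 between HIBD model and normal libraries, 16 higher and 11 lower. With RLE normalization 14 were higher and 5 lower, and with the trend on transcript length removed 16 and 17. Without a filter 5 were higher and 0 lower, and with a filter of at least 1 CPM in 4 libraries 4 and 1. After division of all values by 70, 1 was higher and 0 lower. With Ensembl genes tested alone 2 were higher and 0 lower, so the 11 lower calls did not pass there. In the test of all genes, all 11 genes that fell had an Ensembl identifier, with log2 fold changes from -1.43 to -0.37. Of the 16 that rose, 3 had a mean log2 CPM of at least 0, against all 11 that fell. Among the 16, 14 were assembled loci. Over the HIBD model and acupuncture libraries, these loci had means from 0.0683 to 5.65 CPM before TMM scaling. Of these loci, 11 were listed at 0 in all 4 normal libraries, so no fold change is given for them, and the other 3 had log2 fold changes from 1.77 to 2.98. XLOC_084636 and XLOC_077126, the 2 genes of lowest p, were among those listed at 0. They averaged only 0.161 and 0.0836 CPM in HIBD model libraries, so the calls of lowest p rested on very low values. At an unadjusted p under 0.05 there were 6245 genes, 22.4% of those tested, with 3782 higher and 2463 lower. The number of calls depended on single libraries. It was 5, 3032, 4 and 9 without normal replicates 8, 10, 11 and 13, and 126, 1, 6 and 6 without HIBD model replicates 2, 8, 16 and 18. By method it was 5 with limma-voom and 3751 with DESeq2. It was 0 with edgeR fitted to these 2 groups alone (4986 genes at an unadjusted p under 0.05), where the adjusted p of the 4 named genes lay between 0.0944 and 0.125. It was also 0 with limma-trend on log2(FPKM + 1) (7643 at an unadjusted p under 0.05), against 1387 on log2(FPKM + 0.1). With 1 surrogate variable it was 26, of which 13 were among the 27, and with an on/off class of libraries set by 7 genes as covariate it was 0 in edgeR (5859 at an unadjusted p under 0.05), while the share of genes at an unadjusted p under 0.05 lay between 15.2% and 28.2% over 25 alternatives.

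The assembled loci as a class had higher values in HIBD model than in normal libraries, by a difference that did not pass its exact test with all libraries. Among the 1418 assembled loci with a mean log2 CPM of at least 0, the median log2 fold change was 1.42 and 82.2% were higher, while the 14068 Ensembl genes above the same level had a median of -0.08. Assembled loci took 1.90 ± 0.387% of the estimated counts in HIBD model, 1.79 ± 0.527% in acupuncture and 1.01 ± 0.335% in normal libraries (SD, n = 4). The median over these loci in each library, relative to the mean of the 12 libraries, was -1.48, 0.05, -1.15 and -1.32 on the log2 scale in normal replicates 8, 10, 11 and 13. It was -0.06, 0.82, 1.22 and 0.15 in HIBD model replicates 2, 8, 16 and 18, and 0.96, 0.73, 0.62 and -0.09 in acupuncture replicates 5, 22, 35 and 55. The difference between the group means of these medians was 1.51 between HIBD model and normal (two-sided exact permutation p = 0.0571, adjusted over 3 comparisons 0.0857), with a smallest possible p of 0.0286 for 4 against 4 libraries. It was 1.53 between acupuncture and normal (exact permutation p = 0.0571, adjusted 0.0857) and 0.02 between acupuncture and HIBD model (exact permutation p = 1). Normal replicate 10 lay among the other 2 groups, and without it the differences from normal were 1.84 and 1.86. No p is given for these, because that library was singled out by this same measure.

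**Figure D2:**
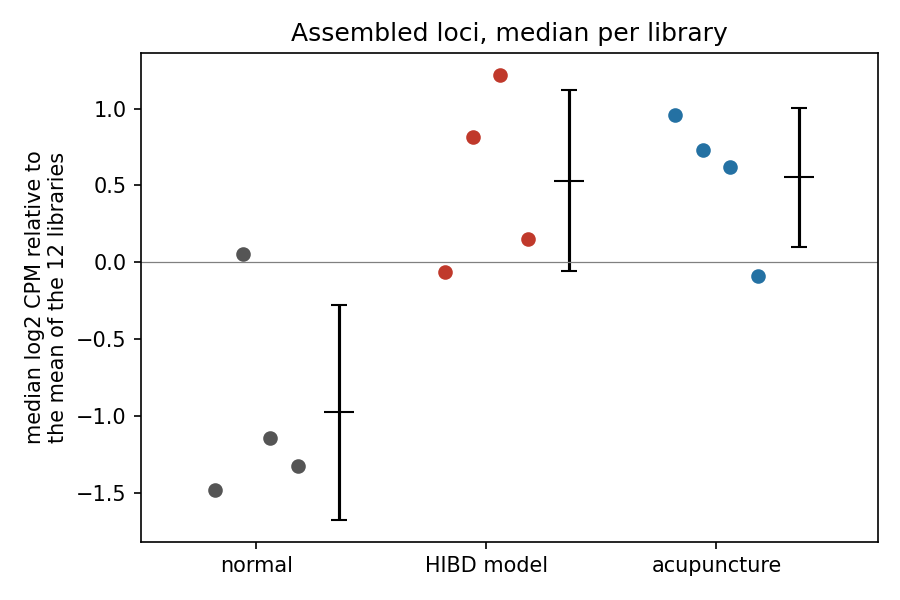
Median log2 CPM of 1418 assembled loci in each library, relative to the mean of the 12 libraries (vertical axis, log2 scale), by group. Points are libraries in the order of their replicate numbers, and bars give the group mean and SD (n = 4). Normal replicates 8, 11 and 13 lie between -1.48 and -1.15, and every other library lies at -0.09 or above.

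The comparison of acupuncture with HIBD model libraries asks what differed after the treatment. No gene passed an adjusted p of 0.05 in edgeR, where the smallest adjusted p was 0.907. At an unadjusted p under 0.05 there were 1481 genes, 5.3% of those tested. Limma-voom also called 0 genes, and DESeq2 called 185. Gene ENSRNOG00000000989 averaged 10.6 ± 1.68 CPM in acupuncture, 6.21 ± 0.145 CPM in HIBD model and 11.9 ± 1.42 CPM in normal libraries (SD, n = 4), with a log2 fold change of 0.78 between acupuncture and HIBD model (SE 0.12, edgeR adjusted p = 0.907). Gene ENSRNOG00000049194 averaged 17.2 ± 5.19 CPM in acupuncture, 6.92 ± 1.37 CPM in HIBD model and 8.89 ± 0.969 CPM in normal libraries, with a log2 fold change of 1.31 (SE 0.22, edgeR adjusted p = 0.907). All 4 acupuncture libraries lay above all 4 HIBD model libraries for both genes, but neither difference passed over all genes tested. Gene ENSRNOG00000010533 averaged 26.1 ± 0.80 CPM in acupuncture, 38.0 ± 5.22 CPM in HIBD model and 35.8 ± 5.06 CPM in normal libraries, with a log2 fold change of -0.54 (SE 0.11, edgeR adjusted p = 0.907). All 4 acupuncture libraries lay below all 4 HIBD model libraries for this gene, which did not pass either. These genes were chosen by lowest p, so such separation adds no support. Gene ENSRNOG00000009577 averaged 9.76 ± 3.37 CPM in acupuncture against 140 ± 133 CPM in the HIBD model group (log2 fold change -3.85, SE 0.83, edgeR adjusted p = 0.907). DESeq2 gave adjusted p-values of 4.81e-07 for ENSRNOG00000000989, 5.81e-06 for ENSRNOG00000049194, 0.00538 for ENSRNOG00000010533 and 1.52e-05 for ENSRNOG00000009577, and all 4 genes missed 0.05 in the other 22 alternatives run. Levels of ENSRNOG00000005927, ENSRNOG00000004926 and ENSRNOG00000054291 in acupuncture libraries were 26.7 ± 1.70, 8.85 ± 0.323 and 17.9 ± 1.60 CPM. The median log2 fold change between acupuncture and HIBD model was 0.01 for Ensembl genes and -0.06 for assembled loci.

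The comparison of acupuncture with normal libraries asks what still differed from normal in the treated group. Gene ENSRNOG00000005927 rose to 26.7 ± 1.70 CPM from 16.1 ± 1.67 CPM in normal libraries, a log2 fold change of 0.73 (SE 0.08, edgeR adjusted p = 0.0177). Gene ENSRNOG00000054291 fell to 17.9 ± 1.60 CPM from 27.1 ± 1.78 CPM, a log2 fold change of -0.59 (SE 0.08, edgeR adjusted p = 0.0423). Gene ENSRNOG00000004926 had a log2 fold change of 0.41 (SE 0.08) that did not pass (edgeR adjusted p = 0.0931, with 0.0233 without normal replicate 10 and 0.1 to 0.265 without any other replicate). Gene ENSRNOG00000009577 averaged 311 ± 123 CPM in normal libraries, and its log2 fold change of -4.99 (SE 0.88) did not pass either (edgeR adjusted p = 0.0714, with 0.0136 without normal replicate 10 and 0.1 to 0.212 without any other replicate). The rule for naming also picked other genes in this comparison, which were not followed singly over the alternatives. ENSRNOG00000006104 fell from 2.04 ± 0.257 to 0.591 ± 0.0788 CPM, a log2 fold change of -1.79 (SE 0.20, edgeR adjusted p = 0.0177). ENSRNOG00000047931 had a log2 fold change of -0.51 (SE 0.06, edgeR adjusted p = 0.0193) and XLOC_049670 of 2.10 (SE 0.27, edgeR adjusted p = 0.0302). The call of ENSRNOG00000005927 was lost without normal replicate 11 or acupuncture replicate 5, 22 or 35 (edgeR adjusted p from 0.05 to 0.0764). The call of ENSRNOG00000054291 was lost without normal replicate 8, 11 or 13 or acupuncture replicate 5, 22 or 35 (edgeR adjusted p from 0.0597 to 0.132).

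In all, 23 genes passed between acupuncture and normal libraries, 14 higher and 9 lower. With the trend on transcript length removed, 17 were higher and 16 lower. Of the 14 that rose in the main test, 2 had a mean log2 CPM of at least 0, against all 9 that fell. Of the 14 that rose, 13 were assembled loci, and 10 of these were listed at 0 in all 4 normal libraries. All 9 genes that fell had an Ensembl identifier, and with Ensembl genes tested alone 1 was higher and 1 lower. At an unadjusted p under 0.05 there were 6834 genes, 24.5% of those tested. The number of calls was 9, 3094, 4 and 7 without normal replicates 8, 10, 11 and 13, and 1, 0, 6 and 34 without acupuncture replicates 5, 22, 35 and 55. It was 9 with limma-voom (4 higher and 5 lower) and 4327 with DESeq2 (2752 higher and 1575 lower). It was 807 with edgeR fitted to these 2 groups alone (351 higher and 456 lower) and 1 with limma-trend on log2(FPKM + 1). With 1 surrogate variable it was 1, which was not among the 23, with 2863 genes at an unadjusted p under 0.05. ENSRNOG00000005927 then had a log2 fold change of 0.76 (SE 0.10, edgeR adjusted p = 0.0764) and ENSRNOG00000054291 of -0.52 (SE 0.10, edgeR adjusted p = 0.232). With the on/off class as covariate it was 0 in edgeR (5795 at an unadjusted p under 0.05), and the share of genes at an unadjusted p under 0.05 lay between 10.3% and 34.9% over 25 alternatives. The median log2 fold change was 1.32 for assembled loci, of which 83% were higher, and -0.08 for Ensembl genes. A test of any difference among the 3 groups called 7 genes in edgeR, with 5736 at an unadjusted p under 0.05.

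Both comparisons with normal shared 13 of their higher calls and 2 of their lower calls, against 0.00803 and 0.00355 for independent lists of those sizes. Both use the same normal libraries, so part of such sharing arises without any effect. Of the 13 shared higher calls, 10 were assembled loci listed at 0 in all normal libraries, which favours a call in both. The numbers for independent lists are therefore a poor reference. Across the 27885 genes tested, which are not independent replicates, the covariance of the 2 sets of log2 fold changes was 1.40, against 0.388 in simulated unchanged groups with shared normal libraries. With the normal libraries split into pairs, so that no library was used on both sides, it averaged 1.03 over 6 splits, with a range of 0.94 to 1.07. Low genes and loci enlarge these values. Among the 15486 genes with a mean log2 CPM of at least 0 the covariance was 0.621, against 0.15 in the simulation. With the split libraries it averaged 0.474 there, with a range of 0.416 to 0.514.

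Whether the acupuncture group moved back towards normal was read from the signs of the fold changes. Of the 27 genes called between HIBD model and normal, 20 had the opposite sign between acupuncture and HIBD model, 74.1%. The HIBD model libraries enter both comparisons. The 27 strongest genes of simulated unchanged groups gave 95.5% opposite signs by that sharing and by their choice. Those groups hold no real change, and for genes that did change the sharing can give fewer opposite signs. Real shares and ratios above or below the simulated ones therefore do not measure a return towards normal. Of the 13 Ensembl genes among the 27, 11 had the opposite sign, 84.6% against 97.2% in the simulation. At an unadjusted p under 0.05, 8 of them did so, 61.5% against 72.7%. Of all 27 genes, 29.6% did so at that p, against 62.6% in the simulation. Of the 500 genes of lowest p, 80.8% had the opposite sign against 92.7%, and 13% had it at an unadjusted p under 0.05 against 38.2%. Whether the simulated p has the same power as the edgeR p was not tested. The shares at that p are therefore not closely comparable with the simulation. All 27 genes kept the sign of their HIBD model change between acupuncture and normal, but the shared normal libraries alone gave 92.2% in the simulation. The median ratio of those log2 fold changes was 0.66 for the 13 Ensembl genes, against 0.34 in the simulation. For the 500 genes of lowest p the ratio was 0.85, against 0.42. No ratio is given for the 27, of which 11 were listed at 0 in all normal libraries. With the HIBD model libraries split into pairs, the share of opposite signs among 500 genes chosen with 1 pair and read with the other averaged 54% over 6 splits, with a range of 22.6% to 68.4%. The covariance of the HIBD model and acupuncture changes was -0.324, against -0.438 in simulated unchanged groups, and it averaged 0.113 with the split libraries, with a range of -0.229 to 0.828. Among the 15486 genes with a mean log2 CPM of at least 0 it was -0.0984, against -0.16 in the simulation. The split libraries averaged 0.0646 there, with a range of -0.0821 to 0.383. These values do not separate a return towards normal from the effect of the shared libraries.

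**Figure D3:**
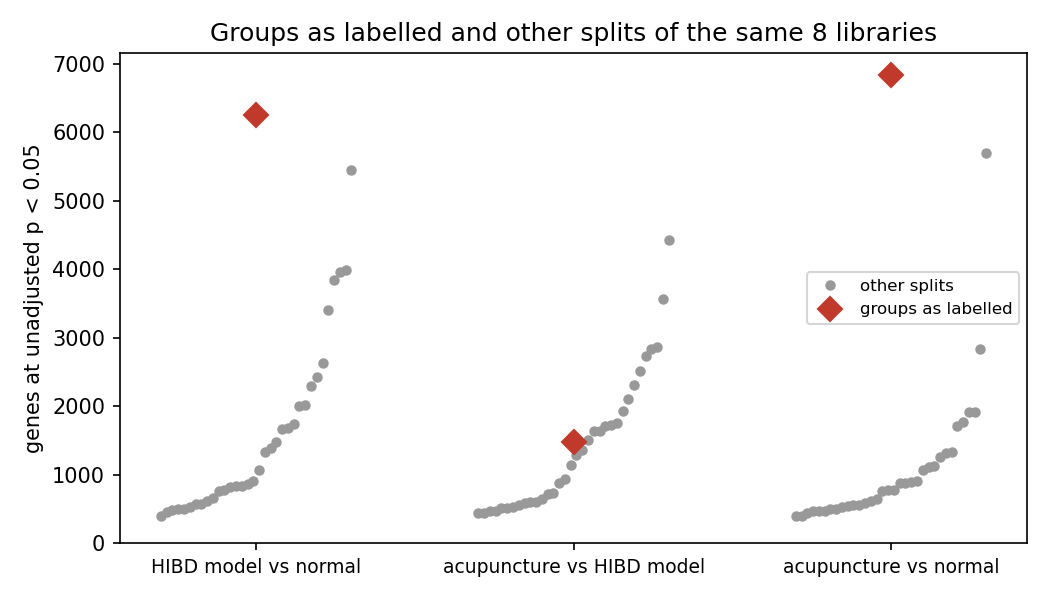
Number of genes at an unadjusted p under 0.05 (vertical axis) in each comparison, for the groups as the labels give them (diamonds) and for the 34 other splits of the same 8 libraries into 4 and 4 (points, sorted by value from left to right). The labelled groups gave 6245 and 6834 genes in the comparisons with normal, above the highest other splits at 5454 and 5691, and 1481 genes between acupuncture and HIBD model, where other splits reached 4432.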

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

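All tests of explanations in this part were chosen after the results were seen. Of 60 groups of 4 libraries examined over 20 measures, 6 held a library far from the other 3, where chance alone gives about 3. Each is given with the gap to the nearest library as a share of the range of the group.

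Normal replicate 10 stood apart in 2 measures. Assembled loci took 1.51% of its estimated counts against 0.8% to 0.87% in the other normal libraries (gap share 0.901), and its slope of log2 CPM on log2 relative transcript length was 0.0046 against -0.0457 to -0.0405 (gap share 0.897). HIBD model replicate 18 had 1090316733 estimated counts against 890562476 to 899545516 (gap share 0.955). HIBD model replicate 2 had 25 of the 1418 assembled loci at 0 against 14 to 15 (gap share 0.909). Acupuncture replicate 55 had a score of 0.09 on the first principal component of Ensembl genes and assembled loci together, against 0.39 to 0.43 in the rest of its group (gap share 0.878). ENSRNOG00000009577 was at 14.7 CPM in acupuncture replicate 5 against 7.33 to 8.54 CPM in its group (gap share 0.836).

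The shift of assembled loci against normal was set against technical explanations. A constant background of reads over all features would raise near-silent genes alike, but the 1623 tested Ensembl genes below 0.1 FPKM in normal libraries gained a median of 0.012 FPKM, 2.03% of the 0.592 FPKM gained by the loci. With the trend on transcript length removed, the smaller of the shifts against normal was still 1.41, with a standard error of 0.46 before removal, which argues against that trend as the whole cause. A gradient between libraries that also runs within groups, such as tissue or RNA state or library preparation, cannot be told apart from the groups. The first principal component of Ensembl genes followed the median of the loci over 12 libraries (Pearson r = 0.83, permutation p = 0.00105, Spearman rho = 0.75, p = 0.00699, 0.78 without the 2 farthest libraries, adjusted p = 0.0021 over 2 relations), but within groups r was 0.65 with a permutation p of 0.07. The injury itself, which the groups name, stays open and untested as an explanation.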

How the results depend on the processing

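Alternatives added after seeing the data are the last 5 named for the numbers of genes and all those for assembled loci. Between HIBD model and normal, 27 genes passed, 19 with RLE, 3751 with DESeq2, 5 with limma-voom, 5 without a filter, 5 with the stricter filter, 0 with only the 2 groups, 18 among transcript rows, 26 with 1 surrogate variable, 0 and 1387 with limma-trend on FPKM at pseudocounts of 1 and 0.1, 27 without the 10 most abundant genes and 16 at an absolute log2 fold change of at least 1. Leaving out each replicate gave 1 to 3032. The added settings gave 0 with the on/off class as covariate, 33 with the length trend removed, 1 after division by 70, 2 among Ensembl genes only and 1275 with quality weights. Between acupuncture and normal, in the same order, 23 became 13, 4327, 9, 11, 8, 807, 30, 1, 1 and 1739, 23 and 15, then 0 to 3094 and 0, 33, 5, 2 and 5082. Between acupuncture and HIBD model, 0 became 185 with DESeq2, 1 with only the 2 groups, 4 among transcript rows and 0 to 1 with each replicate left out, and it stayed 0 in the other settings. For any difference, 7 became 8 with limma-voom and 4 with RLE. The 27 genes were all among those DESeq2 called, and 4 of them were among those limma-voom called. The smaller numbers with a fold minimum and with Ensembl genes only follow in part from fewer genes eligible. For the others the cause was not tested. DESeq2 gave 2684 higher and 1067 lower, against 16 and 11 in edgeR.

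The shifts of assembled loci against normal passed 0.05 in none of the settings run with all 12 libraries. The exact p was 0.0286 with no normalization factor (HIBD model, 1.52) and with the on/off class as covariate (acupuncture, 1.66), but 0.0857 once adjusted over 3 comparisons. Leaving out each replicate gave 1.28 to 1.84 and 1.37 to 1.86, with both highest values without normal replicate 10. Among loci with a mean log2 CPM of at least 3 the shifts were smaller. They were 1.03 for HIBD model and 1.16 for acupuncture, against 1.51 and 1.53 in the main setting. The difference between acupuncture and HIBD model of 0.02 changed sign, to -0.05 with no normalization factor and within -0.18 to 0.26 with each replicate left out, where its sign was not resolved. For 7 genes, 12 pairs of a gene and a comparison were run, and each pair kept its direction over its 23 alternatives, but some sizes moved by over 1.5 times. With limma-trend on log2(FPKM + 1), a scale that shrinks the change of low genes, ENSRNOG00000004926 went from 0.62 to 0.22 in the HIBD model and from 0.41 to 0.11 in acupuncture against normal (0.24 at a pseudocount of 0.1). Between acupuncture and HIBD model, ENSRNOG00000049194 went from 1.31 to 0.55, ENSRNOG00000010533 from -0.54 to -0.32 and ENSRNOG00000009577 from -3.85 to -1.94, and the last was -2.51 with 1 surrogate variable. Between HIBD model and normal, ENSRNOG00000005927, ENSRNOG00000004926, ENSRNOG00000000989 and ENSRNOG00000054291 passed in 15, 10, 11 and 10 of 23. Between acupuncture and normal, ENSRNOG00000005927, ENSRNOG00000054291, ENSRNOG00000004926 and ENSRNOG00000009577 passed in 16, 9, 4 and 5. Between acupuncture and HIBD model, the 4 genes named passed in 1 each. The share of opposite signs was 80.8% for the 500 genes of lowest p and 54% with split libraries.

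Tests of gene lists, with an estimated correlation, fry, RLE and replicates left out, and the covariate from Y-linked genes were not run, because no identifier matched a symbol. Haemoglobin and mitochondrial genes were not removed for the same reason. No paired analysis was possible because the groups share at most 1 replicate number. Depth in reads is unknown, so no limit from counting is given.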

Other observations

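All tests of explanations in this part were chosen after the results were seen. Gene ENSRNOG00000009577 varied widely within 2 of the groups. In the HIBD model group it was at 265 and 245 CPM in replicates 2 and 18 and at 14.6 and 36.4 CPM in replicates 8 and 16. In the normal group it was at 397 and 434 CPM in replicates 10 and 13 and at 185 and 226 CPM in replicates 8 and 11. The acupuncture group averaged 9.76 CPM.

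Other splits of the same libraries were counted for each comparison. For genes past an adjusted p of 0.05, 2 of the 35 splits of HIBD model and normal libraries gave as many as the real 27, and the highest other gave 50, so chance could not be excluded for that number. That other split set normal replicates 8 and 11 with HIBD model replicates 8 and 16 against the rest, the libraries lower in ENSRNOG00000009577 within their groups. For acupuncture and normal it was 2 of 35, with 23 genes and a highest other of 171, from normal replicates 8, 11 and 13 with acupuncture replicate 55 against the rest. That is several times the real number. This split exchanges normal replicate 10 with acupuncture replicate 55, so it alone cannot tell which of them lies apart from its group. Leaving out normal replicate 10 gave 3094 calls, against 34 without acupuncture replicate 55, which singles out the former by that number. Pearson's r across genes was highest with HIBD model replicate 2 for normal replicate 10 (0.9816), against 0.9715 to 0.9723 with normal libraries. For acupuncture replicate 55 it was 0.9704 to 0.9796 in its group and 0.9762 with normal replicate 11. On the first principal component of all genes with a mean log2 CPM of at least 0, both lay nearer the other group. Normal replicate 10 scored -0.092 against -0.776 to -0.513 in its group, and acupuncture replicate 55 scored 0.091 against 0.387 to 0.428. Neither stood apart on the component of Ensembl genes alone. Normal replicate 10 scored -0.218 on it, between normal replicates 8 and 11 at -0.413 and -0.175. Acupuncture replicate 55 scored 0.242 there, between acupuncture replicates 5 and 22 at 0.174 and 0.278. For acupuncture and HIBD model the real number was 0, which every split reaches, so such a count tests nothing there. The highest other split gave 13. For any difference among the 3 groups, 4 of 100 splits, the real one included, gave at least 7 genes, with a highest other of 23. The 3 of 99 drawn splits had an exact binomial 95% interval of 0.629% to 8.6%, so chance was not excluded beyond the error of drawing.

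The number of genes at an unadjusted p under 0.05 separated more clearly. The real split gave the most genes of 35 in both comparisons with normal, 1 of 35 each. It gave 6245 genes against 5454 in the highest other for HIBD model, and 6834 against 5691 for acupuncture. That is the smallest share 35 splits can give. It was not adjusted over the comparisons, which share the normal libraries, so chance was not firmly excluded. Between acupuncture and HIBD model, 16 of 35 splits gave at least the real 1481, with a highest other of 4432, so chance could not be excluded. For any difference, 2 of 100 splits, the real one included, gave at least 5736, with a highest other of 5995. The 1 of 99 drawn splits had an interval of 0.0256% to 5.5%, so chance was not excluded beyond the error of drawing there either. An unequal share across groups of an on/off class of libraries, set by 7 genes, is argued against as the source of this excess, since at least 20.8% of genes were at an unadjusted p under 0.05 with that class as covariate. The same holds for the trend on transcript length, with at least 23.3% once it was removed. With 1 surrogate variable the share was 20.4% between HIBD model and normal, against 22.4% without it, which argues against a gradient held by that variable as the whole source there. Between acupuncture and normal it fell from 24.5% to 10.3%. That variable was below 0 in all 4 normal and above 0 in all 4 acupuncture libraries, so for this comparison such a gradient and the groups cannot be told apart.

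In 6 of the 12 libraries, 6 genes were on and in the other 6 they were off by at least 10-fold, and 1 gene showed the opposite. ENSRNOG00000060496 lay between 38.3 and 46.6 CPM where on and at or below 0.03 CPM elsewhere, and ENSRNOG00000051257 lay between 37.7 and 91.5 CPM in the opposite libraries and at or below 0.09 CPM where the others were on. The class was on in 3 normal, 2 HIBD model and 1 acupuncture libraries. No other pattern with both directions and both classes in every group held more than 4 genes, against 7 here. A candidate explanation is animals of both sexes. This cannot be told apart from linked variants between animals, because the labels give no sex, the identifiers were not matched to names, and the pattern was chosen as the leading one. With the class as covariate, edgeR called 0 genes in both comparisons with normal, with 5859 and 5795 at an unadjusted p under 0.05. The comparison of acupuncture with HIBD model had 0 without it too. The calls of the named genes given next ended because their adjusted p rose to between 0.0534 and 0.141 in edgeR. Their folds were about as large, with 1 residual degree of freedom fewer. Between HIBD model and normal, ENSRNOG00000005927 had a log2 fold change of 0.75 (SE 0.08, edgeR adjusted p = 0.0534) against 0.72 (SE 0.08) without the class. ENSRNOG00000004926 had 0.61 (SE 0.09, edgeR adjusted p = 0.0709) against 0.62 (SE 0.08), ENSRNOG00000000989 -0.95 (SE 0.12, edgeR adjusted p = 0.0579) against -0.93 (SE 0.12), and ENSRNOG00000054291 -0.60 (SE 0.08, edgeR adjusted p = 0.0534) against -0.63 (SE 0.08). Between acupuncture and normal, ENSRNOG00000005927 had 0.78 (SE 0.08, edgeR adjusted p = 0.0606) against 0.73 (SE 0.08) and ENSRNOG00000054291 -0.54 (SE 0.08, edgeR adjusted p = 0.141) against -0.59 (SE 0.08).

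The spread between replicates had its highest value in the HIBD model group, a difference that was not tested. The median SD of log2 CPM over genes was 0.25 there, 0.17 in normal and 0.19 in acupuncture libraries, a ratio of 1.44 to normal. With each replicate left out, the ratio ranged from 1.21 without HIBD model replicate 16 to 1.64 without normal replicate 10. The cause was not tested.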
